A study of Arabidopsis thaliana with 16 samples.

How the data were processed

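Leaf DNA of 16 Ex-TAQing strains (Cy5) was compared with leaf DNA of wild-type Col-0 (Cy3) on 16 two-colour Agilent tiling arrays, from 100 ng of labelled DNA per the labels' protocols, which also give growth for 4 weeks and a heat treatment of the treated plants of 3 h at 33 °C. The protocols name 1 restriction enzyme gene as introduced and another as activated by heat, so that the enzyme is not stated here. The labels give no parents, no second array of any strain and no dye swap.

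The deposited scanner files hold spot intensity values made with Agilent Feature Extraction version 11.0.1.1, per the submitters' processing notes. Per the file headers, processed intensities are background-subtracted, spatially detrended and dye-normalised with a linear factor for each channel, and positions refer to TAIR10. The deposited series table holds log10 ratios of Cy5 to Cy3, which equalled the scanner's own log10 ratios per the file headers, with medians between -0.0007 and 0.0027 across arrays, so that its scale, centring and direction were all known. Flags in the deposited files mark control, outlier and dim spots.

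The log2 ratio of processed red to processed green signal was taken for each non-control probe, spots flagged as non-uniform or as population outliers (33 to 321 per array) were left out, and each array was centred on its median, with no loess or quantile step. Pairs of arrays correlated with r between 0.23 and 0.49 over all probes (120 pairs). Between 418 and 6658 probes per array were not well above background in the wild-type channel. The number of arrays, 1 per strain, limits the precision. The array had no plastid or mitochondrial probes, and transposable elements are not annotated in the table used, so that organelle and repeat probes were not analysed here as a class.

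Each chromosome of each array was segmented by exact penalised least squares, with a penalty of 5 times the noise variance times the natural log of the number of probes, the noise coming from the median absolute deviation of differences between neighbouring probes. A segment of at least 5 probes with a mean at or beyond 0.3 in either direction was called, and called segments of 1 direction with at most 5 probes between them were joined. Events of 1 direction whose overlap was at least 50% of each were placed in 1 region. Single events have no p-value. Gains were compared with losses by an exact binomial test. Gene means over genes with at least 3 probes were tested against 0 with limma version 3.58.1 (R 4.3.3) and Benjamini-Hochberg adjustment. Gene lists were tested against 100000 rotations of the events along the probe order, a gene being inside when at least 50% of its probes were, and event positions against 100000 random placements. Gene-poor windows were the 39 of 240 windows of 500 kb with less than 50% of the median number of protein-coding genes (130.5). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, hmmlearn 0.3.3 and matplotlib 3.10.9 was used, with statmod 1.5.0 in R.

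Genes were placed by position through a RefSeq gene table of assembly TAIR10.1, in which the nuclear chromosomes keep TAIR10 coordinates. Of 37899 genes on the 5 chromosomes, 34791 held at least 1 probe and 10871 had a symbol. Named genes followed a rule set before the data were examined: genes of the 6 lists with at least 2 probes in an event (at most 15), the 10 highest and 10 lowest protein-coding genes with a symbol and at least 3 probes whose whole length lay within an event (at most 2 per event; only 1 gene lay wholly within a gain), at most 10 genes spanning the ends of the events with the largest mean times square root of probes, and the 5 highest and 5 lowest called genes with a symbol in the test of all strains. The 10 events with the largest mean times square root of probes and the longest of each direction were described.

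Some details were left open by these plans and set later: the share of a gene's probes that counts as inside, event ends taken midway between the outermost probe and the next (ends at chromosome ends left out), the noise estimate's scaling and the fixed parameters of the hidden Markov model.

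The steps were tested on simulated data. Events planted in the real arrays were found in 91.2% of 80 cases for losses of 5 probes at -1, 26.2% for 5 probes at -0.7, 60.0% for 20 probes at -0.4 and 92.5% for 50 probes at -0.4. Planted gains were found in 72.5% of 80 cases for 10 probes at 0.6 and 93.8% for 5 probes at 1. After the probes of each array were shuffled, 0 events were called. Shuffling removes any slow change of signal along the chromosome, so this count does not cover false events from such changes. In the gene test on 21418 simulated genes, 100.0% of 50 genes shifted by 0.4 were called, with 0 false calls. The simulated genes had independent noise around 0, so this does not cover false calls from an offset that the real arrays share. Of 200 random lists of 25 genes, 3 had p under 0.05.

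Alternatives set before the data were examined covered normexp background correction with an offset of 50 (on median spot and median background signals, since mean signals were not used here), the series table, subtraction of each probe's median over the 16 arrays, dim and flagged spots, centring on the mode, penalty, minimum probes, threshold, a hidden Markov model with 5 fixed states, joining, overlap, probes per gene, the slide as a random block, and leaving out each strain. Correction for GC content was not run because no genome sequence was used here.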

Results

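Copy number was measured by two-colour array hybridisation in leaf DNA of 16 diploid Arabidopsis thaliana strains of the Col-0 ecotype, each the progeny of a plant treated with Ex-TAQing, a system in which a restriction enzyme gene is introduced and activated by heat. Each strain was hybridised on 1 array, labelled with Cy5, against Cy3-labelled wild-type Col-0 DNA. Every array held 177170 probes of 60 nt on the 5 nuclear chromosomes, with a median spacing of 608 bp. The 16 strains formed a single group, named ExTQ001 to ExTQ016 in the labels and called strains 1 to 16 in that order, and no strain had a second array. Values are mean log2 ratios of strain to wild type over the probes of a region or gene, and the spread given is that of the other 15 arrays over the same probes. The noise of a single probe lay between 0.16 and 0.22 (log2) across arrays, and median net signals lay between 65.8 and 114 in the wild-type channel. Positions are those of the TAIR10 build.

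The first comparison asked which stretches of the genome differed in copy number from wild type in each strain. The clearest differences were 4 losses longer than 100 kb, 3 in strain 3 and 1 in strain 15, which together covered 3031 kb. Strain 15 lost signal over chromosome 2 from 17355552 to 18090026, a stretch of 734 kb with 212 protein-coding genes, where its mean over 1149 probes was -0.68 (probe SD 0.22), or 0.623 times wild type. The other 15 strains lay between -0.07 and -0.01 there. In strain 3 the longest loss of all ran over chromosome 5 from 16059516 to 17174983, 1115 kb with 294 protein-coding genes, at -0.40 (probe SD 0.21, 1689 probes), against -0.04 to 0.01 in the other 15 strains. Its other losses were on chromosome 5 from 3740515 to 4690178 (-0.42, probe SD 0.19, 1484 probes, 265 protein-coding genes) and on chromosome 4 from 16718864 to 16950646 (-0.44, probe SD 0.19, 354 probes, 73 protein-coding genes). The other 15 strains lay between -0.06 and -0.01 and between -0.11 and -0.01 over these 2 stretches. Within each of the 4 losses the level held along the stretch: 4 equal parts of the strain 15 loss lay between -0.71 and -0.66, and those of the longest strain 3 loss between -0.41 and -0.37. The 50 probes on either side of the strain 15 loss averaged -0.02 and -0.04. With normexp background correction the strain 15 loss stood at -0.39 and the longest strain 3 loss at -0.25, short of the threshold of 0.3, and 2 losses were called in all. The offset of 50 in that correction pulls ratios toward 0 by construction, so part of this fall was set by the correction itself.

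**Figure D1:**
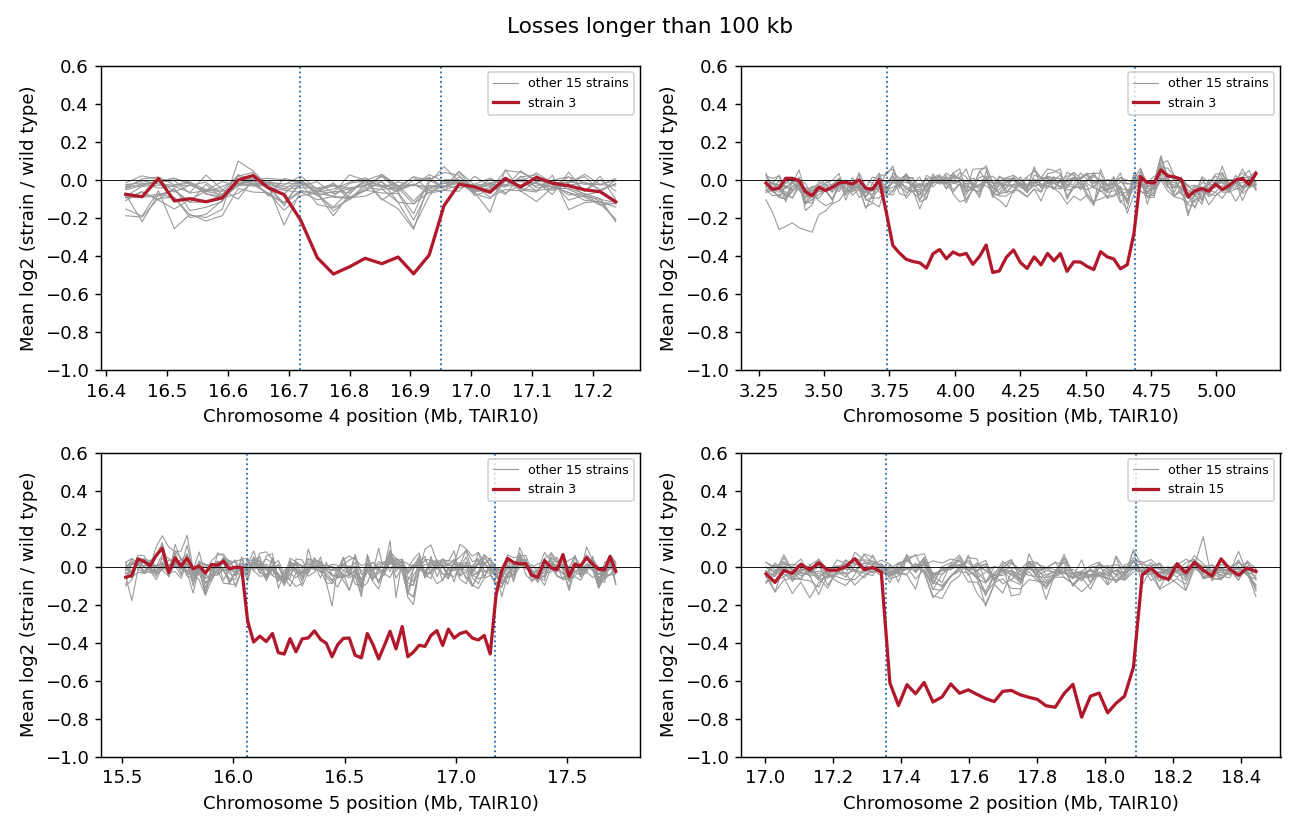
Mean log2 ratio of strain to wild type (y axis) in bins of about 40 probes along the chromosome (x axis, Mb) around the 4 losses longer than 100 kb. The red line is the strain with the loss, grey lines are the other 15 strains and dotted lines mark the called ends. Strain 15 sits at -0.68 within its loss, and strain 3 between -0.44 and -0.40 within its 3 losses.

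The named genes with the lowest means in these losses lay below the level of their stretch, having been selected as the lowest. In strain 15 the lowest were INT1, an inositol transporter of the vacuole membrane, at -0.89 (probe SD 0.15, 5 probes), and RLP29, a receptor-like protein, at -0.85 (probe SD 0.21, 4 probes). The other 15 strains ranged from -0.24 to 0.07 for INT1 and from -0.22 to 0.09 for RLP29. In strain 3 the transcription factor gene RKD5 stood at -0.74, the exocyst subunit gene EXO70C1 at -0.69, the zinc transporter gene ZIF1 at -0.63, the photosystem II assembly factor gene HCF244 at -0.58, the ubiquitin-conjugating enzyme gene UBC8 at -0.56 and the farnesyltransferase subunit gene ERA1 at -0.56, with 3 to 8 probes each. For RKD5 the other 15 strains ranged from -0.47 to 0.07, so that its value lay closer to their range than that of ERA1, for which they ranged from -0.17 to 0.05. The strain 15 loss also held genes with well-known roles, chosen after their values were seen: the light-signalling factor PIF4 (-0.61), the strigolactone signalling gene MAX2 (-0.67), the phase-change factor SPL9 (-0.53), the cold-regulated gene COR15A (-0.60), the fruit-patterning gene SHP2 (-0.84) and the flowering-time gene FPA (-0.63).

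Across all strains, 104 events were called, 83 gains and 21 losses, and each of the 16 strains had at least 1. Strain 4 had the most with 21 and strain 5 the fewest with 2, around a median of 5. Losses occurred in 5 strains. Of the 21 losses, 14 were in strain 4, each between 3.31 and 31.9 kb long with means from -0.73 to -0.32. Among them were chromosome 1 from 28815806 to 28823076 (-0.73, 12 probes), which began in AT1G76780 (-0.70) and ended in IGMT5 (-0.39), chromosome 1 from 12051317 to 12056417 (-0.69, 8 probes), which held the trihelix transcription factor gene GTL1, and chromosome 5 from 13435136 to 13462076 (-0.64, 23 probes), which began in the extensin gene EXT13 (-0.72, 1 probe). Over 8 of these 14 losses the other 15 strains varied more than over 95% of random regions of the same size. The homeobox gene HB-2 stood at -0.65 in strain 4 (probe SD 0.49, 3 probes), while the other 15 strains reached -0.53. At the 1 probe of EXT13 the other 15 strains reached -0.68, close to the -0.72 of strain 4. Strain 6 had a loss of 4.56 kb on chromosome 5 from 18579456 (-0.78, probe SD 0.49, 7 probes), and strain 10 had losses at the start of chromosome 3 (-0.39) and on chromosome 5 from 24621816 to 24660454 (-0.30, 61 probes). The other 15 strains reached -0.50, -0.44 and -0.24 over these 3 losses. Without strain 4, 7 losses remained, and with a threshold of 0.5 on the mean 6 losses were called.

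Gains made up 79.8% of the events (95% exact interval 70.8 to 87.0%, two-sided exact binomial test against equal numbers, p = 6.7e-10), with the caveat that events of 1 strain or of 1 region need not be independent. When each distinct region was counted once, a count chosen after the data were examined, 11 of 31 regions were gains and 20 were losses (35.5% gains, exact binomial p = 0.15). With each probe's median over the 16 arrays subtracted, which removes what most strains share, 5 gains and 32 losses were called. The same step lowers any strain that lacks a shared gain. At the gain on chromosome 2 from 3239649, strain 5 stood at -0.12 before subtraction, against a median of 0.77 over the 16 strains. Part of these losses was thus set by the step itself. Normexp background correction gave 372 gains and 2 losses.

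Whether strains shared events was asked next, since strains from 1 treated parent, or a difference carried by the wild-type DNA, would share them. Of the 31 distinct regions, 9 were called in at least 2 strains, 8 gains and 1 loss, and they held 82 of the 104 events. The remaining 22 regions, 3 gains and 19 losses, were called in a single strain each and fell in 6 strains. A call in 1 strain did not mean that the other strains were at 0. At the gain on chromosome 4 from 5127760, called in strain 2 at 0.38, all 16 strains lay between 0.22 and 0.47, and at the gain on chromosome 4 from 6530510, called in strain 3 at 0.44, between 0.27 and 0.48. Over the loss on chromosome 2 from 15765996, called in strain 4 at -0.32, strain 10 stood at -0.33. A shared gain covered chromosome 2 from 3239075 to 3509176 and was called in 15 strains. It was highest in strain 6 at 1.1 (probe SD 0.23, 442 probes), followed by strain 16 at 0.96, strain 14 at 0.86, strain 10 at 0.84, strain 7 at 0.84, strain 8 at 0.83, strain 4 at 0.82 and strain 1 at 0.77. The lowest called mean was 0.49, and strain 5 stood at -0.12. This stretch lies in the known insertion of mitochondrial DNA into chromosome 2 and was 13.4 times as bright as the median probe in the wild-type channel. The only protein-coding gene with a symbol and at least 3 probes whose whole length lay within a gain was ABCI4, in this stretch, at 0.85 in strain 6 (probe SD 0.18, 9 probes). A gain of 6 probes on chromosome 1 from 24273054 to 24275983, inside the polyubiquitin gene UBQ13, was called in 12 strains, at up to 1.16, and also stood below 0 in strain 5 (-0.13).

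A gain on chromosome 2 from 1490710 to 1501235 was called in 13 strains, with means between 0.90 and 1.09. The stretch common to these calls had 16 probes and overlapped AT2G04300, and in strain 3 the gain ended at AT2G04305 (0.05 over 3 probes). Over those probes strains 2, 5 and 11 stood at 0.00, 0.07 and 0.09, and its brightness in the wild-type channel was 0.553 times that of the median probe. The ribosomal RNA genes at the start of chromosome 2, from 1001 to 11031, gave a higher signal than wild type in all 16 strains (0.61 to 0.96, 18 probes), and those on chromosome 3 from 14191712 to 14204844 were called in 13 strains (0.39 to 0.79 over all 16, 23 probes). In the wild-type channel these 2 stretches were 159 and 150 times as bright as the median probe. Strain 5 was raised here too, at 0.91 and 0.76. With no dye swap, a dye effect or a property of the wild-type DNA cannot be told from more copies at these genes. The longest gain was a pericentromeric stretch of chromosome 5 from 11645768 to 11994478 in strain 10 (0.40, probe SD 0.16, 184 probes, 349 kb). It was called in 6 strains, while all 16 lay between 0.15 and 0.41 over its 160 common probes. A gain of 9 probes over pseudogenes on chromosome 3 from 13536499 to 13541518 was called in strains 1, 3 and 4, all on slide 1, and reached 1.42 in strain 4. All 16 strains lay between -0.22 and 1.42 there, and strains 10, 6, 2 and 16, without a call, stood at 0.73, 0.68, 0.56 and 0.55. The 1 shared loss was at the start of chromosome 3 in strains 4 and 10, and in strain 4 it ended in the transcription factor gene WRKY58. Of the 11 gained regions, 9 were more than 4 times as bright in the wild-type channel as the median probe.

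**Figure D2:**
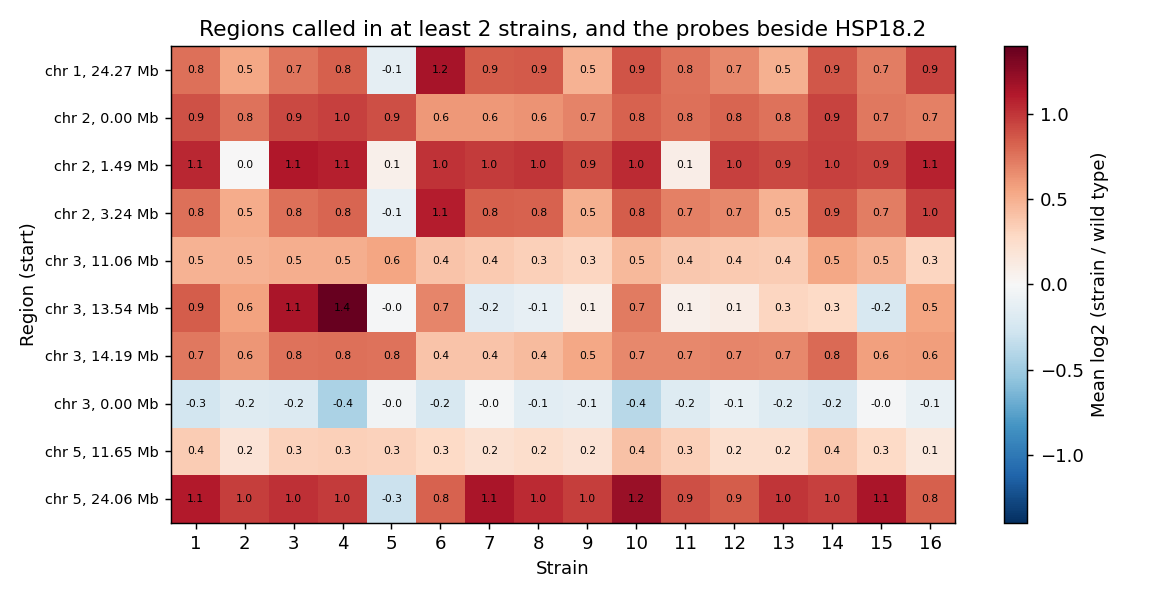
Mean log2 ratio of strain to wild type (colour and printed value) for each region called in at least 2 strains, and for 3 probes beside HSP18.2 on chromosome 5 (rows, named by chromosome and start), in each of the 16 strains (columns). The gain that starts at 1490710 on chromosome 2 is near 0 in strains 2, 5 and 11, and strain 5 is below 0 at UBQ13 on chromosome 1, in the gain that starts at 3239649 on chromosome 2 and beside HSP18.2.

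No chromosome was shifted as a whole in any strain. The 80 chromosome means lay between -0.03 and 0.02, all within the threshold of 0.3, and the SD over the 16 arrays was at most 0.01 on each chromosome. The lowest mean, -0.03 on chromosome 5, was that of strain 3.

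The test of all strains together asked which genes differed from wild type on average. Of 21418 genes with at least 3 probes, 128 were higher and 0 were lower with a mean beyond 0.3 (limma, Benjamini-Hochberg adjusted p under 0.05). They comprised 82 pseudogenes, 31 protein-coding genes, 9 transcribed pseudogenes, 4 other RNA genes and 2 ribosomal RNA genes, and 57 of them lay on chromosome 2. Only 3 protein-coding genes among them had a symbol. UBQ13 was higher at 0.57 ± 0.05 (SE, n = 16, limma adjusted p = 2.1e-09, above 0 in 15 strains), and ABCI4 at 0.55 ± 0.05 (SE, n = 16, limma adjusted p = 6.2e-09, above 0 in 15 strains). VIP2, the neighbour of HSP18.2 on chromosome 5, had a mean of 0.34 ± 0.03 (SE, n = 16, limma adjusted p = 7.1e-08, above 0 in 15 strains), with strain 5 lowest at -0.19. Of its 8 probes, 3 carried this rise, with medians from 0.91 to 1.11 over the other 15 strains, and the remaining 5 had medians from -0.06 to 0.09. With limma, 12279 genes had an unadjusted p under 0.05, and without the threshold on the mean 5373 genes were higher and 5707 lower. Because every array had the same dye orientation and the wild-type channel was the only control, a dye effect or a property of the wild-type DNA enters this count, and the control's own spread is left out.

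Genes of 6 lists fixed before the data were examined were rarely inside events. Within the losses of strain 3 lay ATR, a checkpoint kinase of the DNA damage response (-0.31, probe SD 0.13, 18 probes), FY, a polyadenylation factor of the flowering-time pathway (-0.45, probe SD 0.25, 9 probes), MRN1, the marneral synthase gene (-0.34, probe SD 0.23, 8 probes), HSP17.6II, a small heat shock protein gene (-0.28, probe SD 0.04, 2 probes), and AT5G41750 of the disease resistance list (-0.35, probe SD 0.15, 8 probes). Thus 1 of 32 genes for DNA repair and damage signalling, 1 of 28 for disease resistance, 1 of 23 for flowering time, 1 of 15 for the heat shock response, 1 of 12 for specialised metabolism and 0 of 21 for cell cycle and organ size lay inside events. Random rotations of the events gave means of 1.06, 0.931, 0.765, 0.493, 0.398 and 0.687 genes in the same order. No list differed from the rotations (two-sided permutation test, Benjamini-Hochberg adjusted p = 1 for each of the 6 lists). In the test of all strains together (limma), 30 of the DNA repair genes, 27 of the disease resistance, 22 of the flowering time, 7 of the heat shock, 12 of the specialised metabolism and 19 of the cell cycle genes had at least 3 probes, and 0 of these tested genes were called, adjusted over the list alone or over all genes tested.

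Event ends fell inside annotated genes less often than at random. Of 190 ends, 51.6% lay in a gene, against a mean of 66.6% for random placement on the same chromosomes (two-sided permutation test, p = 4e-05). Shared regions enter this count once per strain, so that the ends are not independent. With 1 event per distinct region, a count chosen after the data were examined, 46.7% of 60 ends lay in genes, against 67.2% at random (permutation p = 0.00082). Without the regions bright in the wild-type channel, 66.7% of 66 ends lay in genes (permutation p = 0.93), and with the probe medians subtracted it was 62.2% (permutation p = 0.44). Genes at the ends of events included AT5G40140 at the start of the longest loss of strain 3 (0.22 over 3 probes), AT5G35200 next to the strain 4 loss at EXT13 (-0.10), PRHA (-0.28) and AT2G46780 (-0.40) in strain 4. The lowest of the other 15 strains reached -0.28 for PRHA and -0.36 for AT2G46780. Gene-poor windows of 500 kb held 12% of the event length, against 16.9% at random (permutation p = 0.59). With a threshold of 0.2 on the mean the share was 51.2% against 15% at random (permutation p = 2e-05, the smallest the permutations can give). Shared regions enter these shares once per strain too, so that the events are not independent. At the threshold of 0.3, 1 event per distinct region gave 4.5% against 15.1% at random (permutation p = 0.68). Without the regions bright in the wild-type channel it was 0% against 15% (permutation p = 0.0044). Both settings were chosen after the data were examined, and neither was tried with the threshold of 0.2.

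The number of events per strain did not follow array noise over the 16 strains (Pearson r = -0.10, permutation p = 0.72, and Spearman rho = -0.25, permutation p = 0.35). This noise comes from differences between neighbouring probes, in which slow changes of signal along the chromosome largely cancel. The relation therefore does not cover array quality of that kind. Without strains 7 and 8, the 2 farthest from the median noise, r was 0.12 (permutation p = 0.71) and rho -0.040 (permutation p = 0.89). Within the second scan day, with 11 strains, r was -0.29 (permutation p = 0.39) and rho -0.37 (permutation p = 0.27). The first day held 5 strains and each slide at most 4, too few for a value. The adjusted p of r over these 3 relations and the 1 without strain 4 (r = -0.30, permutation p = 0.28) was 0.72 for each (Benjamini-Hochberg).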

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

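The settings that count each region once, leave out bright regions or leave out strain 4 from the correlation were chosen after the data were examined; the other settings were not. The series table, centring on the mode, keeping flagged spots, leaving out dim probes, no joining and a minimum of 3 or 10 probes kept the numbers of events, gains and losses within 1.5 times, and no whole-chromosome shift was called with normexp, the series table or centring on the mode, the 3 settings tried for it. Of 111 alternative values for named genes and events, 86 stayed within the spread of their probes, 24 moved beyond it and 1 changed sign. That spread is the SD of single probes, which for long events is far wider than the error of a mean. For the longest loss of strain 3 it was 0.21, against an SE over probes of 0.0051. A value counted as within it may thus still have moved clearly. Normexp background correction gave 374 events (372 gains, 2 losses, 21431 kb) and 396 higher genes, and AT5G35200 in strain 4 moved to 0.018. Subtracting probe medians gave 37 events (5 gains, 32 losses, 3823 kb) in 9 strains, a gain share of 13.5% (exact binomial p = 7.4e-06), 2 shared regions and 62.2% of ends in genes. A penalty of 2.5 gave 263 events (164 gains, 99 losses) with 16.6% of length in gene-poor windows, and a penalty of 10 gave 66 events with 6 losses. The threshold of 0.2 gave 40 losses, 28478 kb and 51.2% of length in gene-poor windows, and 0.5 gave 6 losses and 5049 kb. The hidden Markov model called 663 events (390 gains, 273 losses, 17022 kb). Without bright regions there were 34 events (14 gains, 3438 kb, gain share 41.2%), with 66.7% of ends in genes and 0% of length in gene-poor windows (permutation p = 0.0044). Counting each region once gave a gain share of 35.5%. The count of higher genes was 396 with 1 probe per gene (55 lower), 58 with 5, 46 with a threshold of 0.5, and 5373 with no threshold (5707 lower), against 128. List counts crossed the random mean, never with an adjusted p under 0.05 (Benjamini-Hochberg, permutation tests), in these cases: disease resistance 1 (penalty 2.5, threshold 0.2) and 0 (threshold 0.5), DNA repair 1 (penalty 10, probe medians), and flowering time 2, heat shock 1 and metabolism 1 (threshold 0.2) or 0 each (threshold 0.5). Leaving out each strain gave 7 to 21 losses, with the lowest without strain 4. The fall in gains after probe medians were subtracted follows from what that step removes. It also turns the lack of a shared gain into a loss, so part of the 32 losses and of the lower gain share was set by it. The normexp offset of 50 was not small beside median net signals of 65.8 to 114 in the wild-type channel. Adding it pulls log2 ratios toward 0 by construction, so part of the fall in losses was fixed by that setting. The normexp values also lacked the linear dye factor for each channel, whose effect on the gains was not tested. The cause of the other changes was not tested either. GC correction was not run, and signal over background limits the dimmest arrays, where up to 6658 probes were not well above background. No paired analysis was possible because the strains form 1 group.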

Other observations

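All tests in this part were chosen after the values they concern were seen, except the comparison with equally bright probes.

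Beside the heat shock gene HSP18.2 on chromosome 5, 3 probes from 24060779 to 24062091, in its neighbour VIP2, were higher in 15 strains, with means between 0.82 and 1.21, while strain 5 stood at -0.31. With a minimum of 3 probes in place of 5 it was called in 9 strains. A dye effect common to all arrays would have raised strain 5 too, and its -0.31 argues against that. Strain 5 was, however, the only strain on slide 2, so an effect limited to the other slides cannot be told apart. A property of the wild-type DNA stays open, since strain 5 is the 1 strain without the gain and could itself be wild type. The raised stretch ran into HSP18.2, whose nearest probe had a median of 0.46 in the 15 strains and stood at 0.02 in strain 5; the 5 probes on that side, this one included, averaged 0.070, which cannot tell whether this is an introduced copy, since the 3 probes were chosen for standing out from their neighbours. The chromosome 2 gain at 1490710 does not travel with it, since 2 strains (2 and 11) carry only the gain beside HSP18.2. A single insert of both is thus argued against. Whether strain 5 lost the gain, never had it, is mislabelled or differs through its slide was not tested.

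The gain at chromosome 2 from 3239075 to 3509176 varied between 0.49 and 1.1 among the 15 strains that showed it. Equally bright probes outside all called regions had a median log2 ratio of 0.12 on the same arrays. Leaving out called regions removes bright probes that were raised themselves, which may lower this median. The pericentromeric gain on chromosome 5, so left out, was 12.7 times as bright as the median probe and had a median of 0.28 over the 16 strains. Both values lay below 0.49, which argues against dye bias of bright probes as the whole cause. At this brightness 1 extra homozygous nuclear copy would add at most 0.10, below the lowest value, which argues against a single duplication if signal adds up with copies. The mitochondrial insertion in UBQ13 on another chromosome followed it over the 15 strains (Pearson r = 0.99, permutation p = 1e-05; Spearman rho = 0.98, permutation p = 1e-05, the smallest the permutations can give), also without the 2 farthest strains (r = 0.99, 13 strains) and within the second scan day (r = 0.99, 11 strains; adjusted p = 1e-05 for each of the 3, Benjamini-Hochberg). The gain may thus reflect more mitochondrial DNA in these leaf extracts than in the wild-type extract; whether treatment or extraction set it stays open.

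Over 8 of the 14 small losses of strain 4 the other 15 arrays varied more than over 95% of random regions of the same size, as they did over all 3 small losses of strains 6 and 10, which lay between 1.97 and 4.35 SD of the other arrays below their median. A signal wave between arrays may thus contribute to small losses. Over the probes of strain 4's 14 losses together, the other 15 arrays averaged between -0.20 (strain 10) and -0.02 (strain 7), against -0.42 in strain 4. The 14 lay between 1.96 and 5.92 SD below the other arrays, the farthest among the 8. They were called for being low in strain 4, so this distance cannot tell a loss of DNA from a wave, and both stay open for them. The 4 losses over 100 kb lay at least 13.1 SD of the other arrays below their median. Over none of the 4 did the other arrays vary more than over 95% of random regions. This argues against a wave of the size seen in the other arrays. These losses were also called for being low, so the distance cannot exclude a wave private to 1 array. Strain 3's losses averaged 0.611 times that of strain 15 (-0.42 and -0.68). The chromosome 2 gain at 1490710 was 1.2 times as high in strain 3. This cannot tell whether the array of strain 3 responded more weakly, since the copies of that gain in each strain are not known. A weaker response therefore stays open. Loss of 1 of 2 copies in every cell would give -1 if signal were proportional to copies. The levels of strain 15 (-0.68) and strain 3 (-0.42) both fell short of that. A loss carried by only part of the sampled cells or plants may be an explanation in either strain, and of the shallower level in strain 3. This was not tested. No event of known copy number was at hand to set the scale, so the number of copies lost stays open for both strains.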
